A study of Caenorhabditis elegans with 4 samples.

How the data were processed

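ChIP-seq of a GFP-tagged LSY-2 was done in embryos of Caenorhabditis elegans in 2 ChIP samples, each with an input sample made, per the labels' protocols, from 10% of the same kind of lysate. Cells were fixed in 2% formaldehyde and quenched in 100 mM Tris. Samples were grouped by their titles into LSY-2 GFP ChIP (2) and input (2). The labels do not say whether the replicates came from separate cultures, and none of the tests is across samples, so the p-values describe peaks or stretches of chromosome in these libraries.

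The deposited peak lists give a position and a score for each peak in genome build WS220. Per the file headers they come from the caller SPP followed by IDR. IDR is a procedure that measures how consistently ranked peaks recur between replicates. Each replicate has a list of its own and 1 list is a combined one. Whether reads were pooled for it, the aligner, the tool versions and the thresholds are not given in the sources used here. The scale of the score is not given either. It has a maximum per list at which many peaks tie, 1901 in replicate 1, 3814 in replicate 2 and 3149 in the combined list, so it was used to describe and rank peaks within a list and, between the replicates, only for the correlation of matched peaks. Ties were ordered by the number in the peak's name, which in the replicate lists followed the score (Spearman's rho -1.00 and -0.999) apart from upward steps of at most 0.000228 and 0.000146. In the combined list rho was -0.606, since most scores tie. The 520 peaks below its maximum all had numbers of 3150 or higher, with rho -0.939 among them. That the number is a rank is not stated in the sources used here, so the order of the tied peaks rests on an assumption. Ranked instead by their mean rank in the replicates, 949 of the 1000 highest ranked combined peaks were the same. Each replicate list has exactly 30000 peaks, so its length measures no amount of binding, and its lower ranks can hold background. Depth per sample is unknown, and intervals cover counting of peaks only.

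A peak was shared if it overlapped a peak of the other list by at least 1 bp. Overlap was tested with 1000 circular shifts of 1 list along the span of each chromosome, the span being the first to the last base in the 3 lists. Peaks were paired one to one where they overlapped and were each other's nearest midpoint. Correlations were tested with 100000 shuffles. Shares of peaks have exact Clopper-Pearson 95% intervals. Counts per chromosome were tested with exact binomial tests against the share of the span. As a check that does not treat peaks as independent, 500 kb bins were permuted. The check treats bins as independent, and whether neighbouring bins resemble each other was not tested. Counts in windows of 50 kb were set against 1000 random placements of as many peaks on each chromosome. Adjustment was by Benjamini-Hochberg within each family. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated lists of 3669 peaks with a planted overlap of 51.3% the overlap step recovered 51.3%. It recovered a planted rank correlation of 0.903 as 0.896 and a planted X ratio of 0.646 as 0.601. Of 40 pairs of unrelated simulated lists 1 was called. The rank correlation was recovered only from pairs with close midpoints, a limit that was not set on the real pairs. Simulated peaks were placed at random and their scores did not tie. These values therefore do not cover crowded peaks, tied scores or whole lists of 30000 peaks.

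The overlap, score, combined list and chromosome tests, their first set of alternatives, and the rule that the 20 highest ranked combined peaks be named were chosen before the data were examined. The comparisons by rank, the dense windows and the mitochondrial peaks were chosen after. For the dense windows, the test of whether 1 replicate alone gave them was changed 2 times after its results were seen, as stated where it is reported. Reciprocal overlap was tested with 100 shifts in place of 1000.

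No genome or annotation of build WS220 was used here, and the gene table that was used is of another assembly, WBcel235, so it served only to look up the chromosome of lsy-2 and unc-119. For that reason promoter shares, gene lists drawn up for ASE neurons and other themes, noncoding RNA genes, sequence words at peaks and peaks near the transgene's genes were planned and not analysed here, and peaks carry no gene names. Comparisons with input were not made, since no values of the inputs were analysed here.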

Results

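LSY-2 is a zinc finger transcription factor of the nematode Caenorhabditis elegans, known for its part in making the left and right ASE taste neurons different from each other. Its genomic binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in embryos of a strain that carries an LSY-2 GFP fusion transgene together with unc-119, a gene used to mark transformed animals. The population held males and hermaphrodites and was grown at 20 °C. Chromatin was fixed with 2% formaldehyde and precipitated with antibodies against GFP. The series has 4 samples, 2 LSY-2 GFP ChIP samples and 2 input samples of total chromatin DNA. Peak lists of the 2 ChIP samples and 1 combined list were analysed, and no values of the inputs were analysed here. Read counts were not used, so the depth behind each peak is unknown.

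The authors' combined list held 3669 binding regions, all on the 6 nuclear chromosomes I, II, III, IV, V and X, and covered 1.21 Mb of a summed span of 100.2 Mb. The list of replicate 1 held 30000 regions covering 10.9 Mb, and that of replicate 2 also held 30000, covering 10.3 Mb. In the combined list 71.1% of peaks had the same width of 370 bp. The best peaks were wider, and the 20 highest ranked measured 435 to 567 bp. Of ranks 1 to 500, 0.6% had the common width, against 82.2% of the remaining ranks. In replicate 1, 98.2% of peaks had a width of 380 bp, and in replicate 2, 98.1% had one of 356 bp. The authors' score reached its maximum of 3.80 in 3149 combined peaks, or 85.8%, and therefore ordered few of them. The number in each peak's name was used as its rank, a reading that the sources used here do not state.

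The 20 highest ranked combined peaks were found near the top of both replicate lists, none below rank 32 in replicate 1 or rank 24 in replicate 2. Chromosomes II and III held 6 each, IV held 4, I held 3, X held 1 and V held 0. Coordinates are those of genome build WS220, and genes were not assigned to them because no annotation of that build was used here. The first was IV 4749792 to 4750352, rank 2 in replicate 1 and rank 1 in replicate 2. The next was III 3867253 to 3867819, rank 1 and rank 2. III 4475350 to 4475868 held ranks 3 and 4, and III 12904824 to 12905352 ranks 4 and 3. IV 654682 to 655173 held ranks 7 and 5. The single X region among them, X 15840966 to 15841483, held ranks 5 and 6. I 9619756 to 9620234 held ranks 6 and 9, and II 10868680 to 10869142 ranks 11 and 7. II 8184911 to 8185388 held ranks 8 and 11, and III 6971803 to 6972292 ranks 12 and 10. The other 10 were, in rank order, I 14469096 to 14469565, II 13872359 to 13872841, II 3076882 to 3077343, IV 11566094 to 11566528, IV 8432720 to 8433218, II 14349355 to 14349869, III 7207812 to 7208308, III 13462778 to 13463251, I 4584629 to 4585113 and II 5055146 to 5055608. All 20 had the maximum score of their list in each of the 3 lists.

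Whether the 2 ChIP samples located the same regions was asked by overlapping their lists. The strongest regions were shared and the weak ones mostly were not. Among the 100 highest ranked peaks of each list, 92% of those of replicate 1 overlapped one of replicate 2 by at least 1 bp. This share was 85.1% at a depth of 500 peaks, 76.8% at 1000, 70.8% at 3669 and 47.6% in the whole lists. After circular shifts along each chromosome the mean overlap was 0.332% at 500 peaks, 2.81% at 3669 and 20.9% in the whole lists. The observed overlap exceeded all 1000 shifts at each of the 9 depths (one-sided permutation p = 0.001 at each, the smallest the shifts can give). Of the 496 nuclear peaks among ranks 1 to 500 of replicate 1, 495 overlapped some peak of replicate 2, whatever its rank. Of the lowest 10000 ranks of replicate 1, 32.9% did so, and 32.5% in the reverse direction. Midpoints of matched peaks lay a median of 9.5 bp apart for ranks 1 to 500 of replicate 1 and 120 bp apart for its lowest 10000 ranks.

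**Figure D1:**
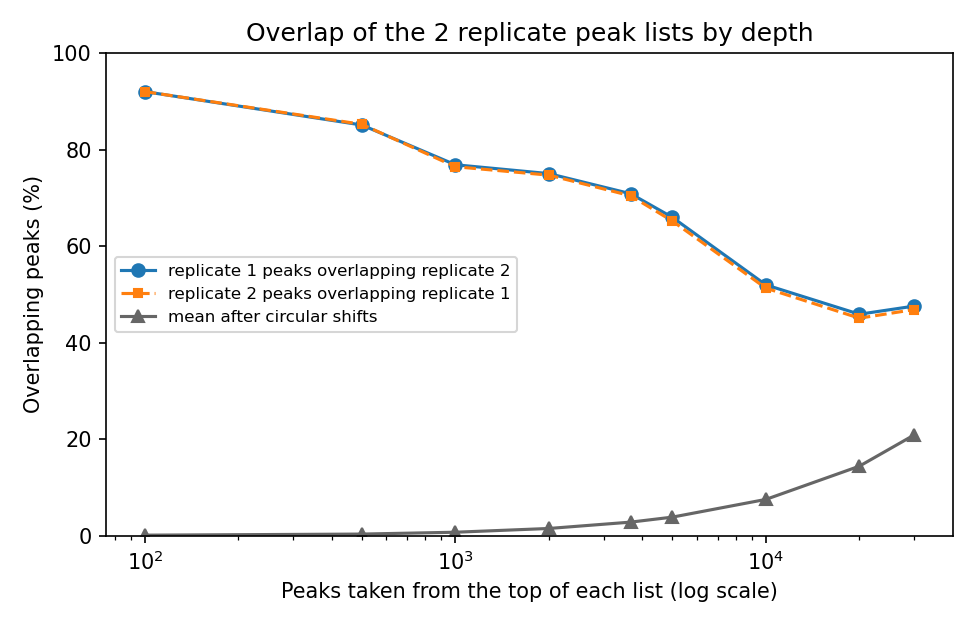
Percentage of peaks of each replicate that overlapped a peak of the other by at least 1 bp (y axis) against the number of peaks taken from the top of each list (x axis, log scale). The triangles are the mean of 1000 circular shifts of replicate 2. The observed overlap fell from 92% at 100 peaks to 47.6% in the whole lists while the shifted mean rose to 20.9%.

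Scores of the peaks that the 2 samples shared rose together. Across 12751 pairs of nuclear peaks matched one to one, Spearman's rho of the scores was 0.570 and Pearson's r of the log10 scores was 0.564 (two-sided permutation p = 1e-05 for each, the smallest that 100000 shuffles can give). Among the 3699 pairs at a combined peak, rho of the scores fell to 0.2504, while rho of the ranks was 0.663. In 1687 pairs both scores stood at the maximum of their list. Among the 9052 pairs away from the combined list, rho of the scores was 0.153. These values are across peaks, which are not independent replicates.

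The combined list was set beside the lists of the single samples to see which regions it kept. Nearly all of its regions were in both: 3640 of 3669, or 99.2% (exact 95% interval 98.9% to 99.5%). Since IDR measures how consistently peaks recur between replicates, this share may follow from how the list was made. It is not separate evidence that the replicates recur. Replicate 1 alone held 10 of the others, replicate 2 alone held 19, and at this overlap of at least 1 bp 0 were in neither. At a reciprocal overlap of 50%, 83.4% were in both and 365 peaks were in neither. The combined peaks were not copies of the replicate peaks, since 0 of them had the coordinates of a peak in either list. Of ranks 1 to 500 in the combined list, 99.8% lay within the first 3669 ranks of both replicates, against 34.2% of combined ranks 2001 to 3669.

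Binding regions were densest on chromosome III and sparsest on V and X. Chromosome III held 839 combined peaks, 60.9 per Mb and 1.66 times the number its span would give. Chromosome I held 742, 49.3 per Mb and 1.35 times. Chromosome V held 448, 21.4 per Mb and 0.585 times, and X held 426, 24.1 per Mb and 0.657 times. The 5 autosomes together held 39.3 per Mb. By exact two-sided binomial tests with Benjamini-Hochberg adjustment over the 6 chromosomes, adjusted p was 3.02e-49 for III, 4.20e-17 for I, 2.10e-42 for V and 9.15e-24 for X. The binomial tests treat peaks as independent, and the bin tests that follow treat neighbouring bins as independent. With bins of 500 kb as units, permutation tests gave adjusted p = 3e-05 for III, 0.00057 for I, 3e-05 for V and 0.00026 for X. Chromosomes II (640 peaks, 1.14 times, adjusted p = 0.00034) and IV (574 peaks, 0.899 times, adjusted p = 0.00464) stood nearer to their spans. With the bins as units the ratios to the other chromosomes were about as large, 1.17 and 0.888, and no longer passed the test (permutation adjusted p = 0.16 and 0.29).

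Along the chromosomes, 53.0% of combined peaks lay in the central 50% of each span (exact 95% interval 51.3% to 54.6%, exact binomial p = 0.000361). Chromosome V had 62.9% there and chromosome I 57.4% (exact binomial adjusted p = 2.81e-07 and 0.000183). X had 43.9% (exact binomial adjusted p = 0.0268), and II, III and IV had 50.6%, 49.8% and 53.3%, with adjusted p of 0.938, 0.945 and 0.184. The X value did not pass the test in the first 3669 ranks of replicate 1 (47.1%) or replicate 2 (48.0%) or with peaks within 5 kb merged (45.8%, exact binomial adjusted p = 0.134). With merged peaks II and III did pass, at 56.3% and 55.5% (exact binomial adjusted p = 0.0184 for each). These binomial tests treat peaks as independent, and the central shares were not checked with bins. The fullest bin of 1 Mb was III 1000968 to 2000967 with 125 peaks, followed by III 8000968 to 9000967 with 79 and II 2000166 to 3000165 with 74.

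**Figure D2:**
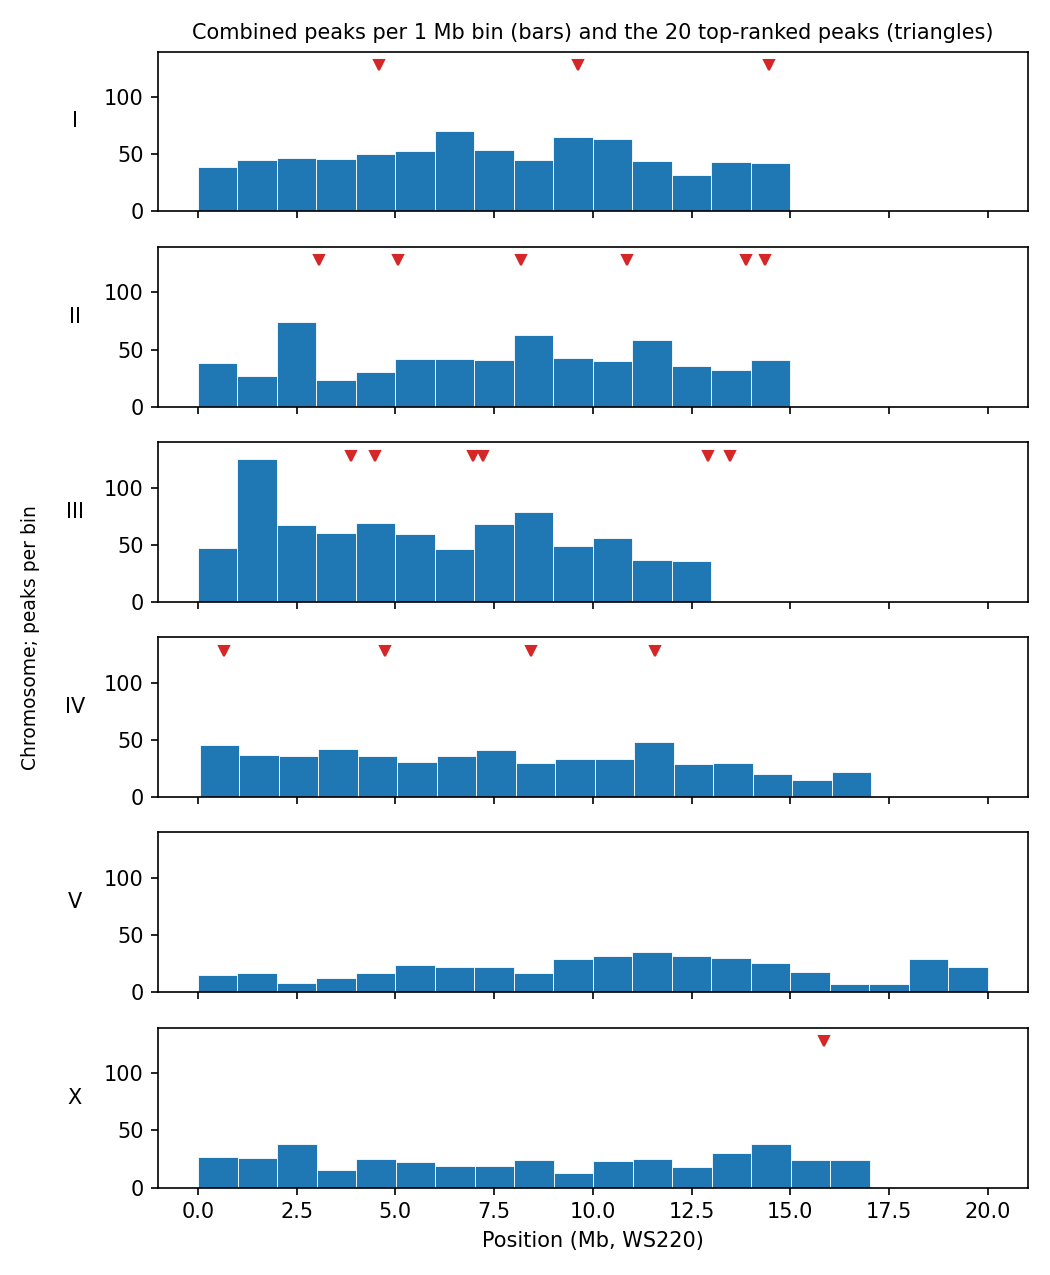
Number of combined peaks in each complete 1 Mb bin (bars, y axis) along each chromosome (x axis, Mb in WS220), with the 20 highest ranked peaks as triangles at a fixed height. The fullest bin, on chromosome III, held 125 peaks, and none of the 20 lay on chromosome V.

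The X chromosome was poorest in strong regions. Of the 1000 highest ranked combined peaks 70 were on X, or 7% (exact 95% interval 5.50% to 8.76%), against 13.3% of the other 2669 (odds ratio 0.489, Fisher's exact test, two-sided, adjusted p = 1.93e-07 over 6 tests). The same comparison within the first 3669 ranks gave 7.99% against 12.8% in replicate 1 and 8.09% against 14.1% in replicate 2 (Fisher's exact adjusted p = 4.88e-05 and 1.84e-06). In the lowest 10000 ranks 16.18% of peaks were on X in replicate 1 and 16.21% in replicate 2, nearer to the 17.7% of the span that X makes up. Strong regions were also more central: 59.2% of the 1000 highest ranked combined peaks lay in the central 50% of their chromosome, against 50.6% of the rest (Fisher's exact adjusted p = 6.83e-06). In the replicates it was 57.4% in each, against 51.9% and 52.4% (Fisher's exact adjusted p = 0.00382 and 0.0064). From the first 1000 ranks to the lowest 10000 the central share differed by a mean of 10.3 percentage points (SD 10.0, n = 6 chromosomes) in replicate 1, where it was higher in 5 of 6 (exact sign permutation p = 0.0938). In replicate 2 the mean was 10.9 points (SD 7.91, n = 6), higher in 6 of 6 (exact sign permutation p = 0.0312, the smallest that 6 chromosomes allow).

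**Figure D3:**
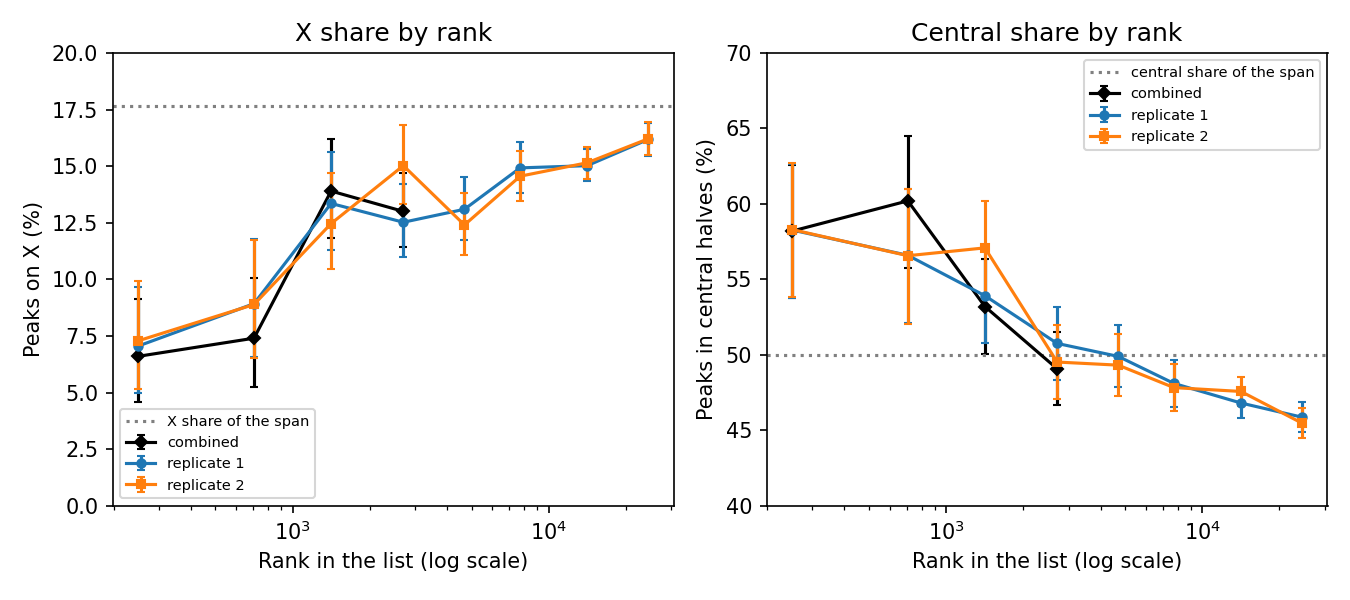
Percentage of peaks on X (left) and in the central 50% of each chromosome (right, y axis starting at 40%) against rank in the list (x axis, log scale), for the combined list and each replicate, with exact 95% binomial intervals as bars and the share of the span dotted. The X share of the combined list was 6.6% in ranks 1 to 500, and in the lowest 10000 ranks it was 16.18% in replicate 1 and 16.21% in replicate 2.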

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

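The tests in this part were chosen after the mitochondrial peaks had been seen. Mitochondrial DNA lies outside the comparisons above, yet the list of replicate 1 held 27 mitochondrial peaks and that of replicate 2 held 24, with best ranks of 336 and 208, while the combined list held 0. In both lists 11 of them stood within the first 1000 ranks. No mitochondrial value of the inputs was analysed here.

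A raised mitochondrial background is a candidate explanation. The mitochondrial length was taken as 13857 bases, the last base seen in the lists, since no genome of this build was used. The peaks covered 59.0% of that length in replicate 1 and 51.3% in replicate 2. Both lay above every one of 7227 nuclear windows of that length, whose highest values were 47.7% and 42.2%. Whether mitochondrial peaks were left out before the combined list was made stays open, since no file header states it. The combined list held 744 of 748 nuclear pairs ranked within 1000 in both replicates, or 99.5%, and there were 7 mitochondrial pairs of such ranks. Of the mitochondrial peaks of replicate 1, 88.9% overlapped one of replicate 2, against a mean of 86.3% after shifts (permutation p = 0.45). With coverage this dense, the overlap cannot tell whether mitochondrial peaks recur. The 7 pairs were not tested on their own and are not comparable with the nuclear pairs. No biological explanation was tested.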

How the results depend on the processing

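Of 92 values recomputed under alternatives, 76 kept their side of the threshold or, with no test, their interval. Among these 76, the central share of III changed direction in the first 3669 ranks of either replicate's own list. It lay below 50% in the combined list and above 50% in the replicates, and passed the test in none of them. Merging peaks within 5 kb, omitting windows of 10 or more peaks, using 500 kb bins, name numbers or mean replicate ranks, and every alternative for the 1000 highest ranked peaks were chosen after seeing the data. Chromosome II no longer passed the test with merged peaks (1.05 times) or bins (1.17), nor IV with merged peaks (0.920), without the dense windows (0.942) or with bins (0.888). With bins the ratios did not shrink, and bins are fewer units. For the others the cause was not tested. The central share of X no longer passed in the first 3669 ranks of either replicate's own list (47.1% to 48.0%), merged (45.8%) or without the dense windows (44.95%). That of II passed merged (56.3%) and without the dense windows (55.8%), and that of III in the better 50% of the list (57.4%), merged (55.5%) and without the dense windows (55.7%). The cause was not tested. The share of combined peaks in both replicates moved from 99.2% to 83.4% at a reciprocal overlap of 50% and to 97.3% with the better 50% of each replicate list, stricter criteria in each case.

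Overlap of the whole replicate lists was 33.7% at a reciprocal overlap of 50% and 25.4% by midpoints within 100 bp. It was 47.3% between the better 50% of each list, and each of these exceeded its shifts. With the combined peaks ranked by their mean rank in the replicates, the odds ratios of the 1000 highest against the rest were 0.498 for X and 1.39 for the central share.

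No paired analysis was possible because no values of the input samples were analysed here. The other settings meant for promoters, gene lists, noncoding RNA and sequence words were not run because no WS220 annotation or genome was used here. Depth is unknown, so how far it limits the weaker peaks cannot be given.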

Other observations

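The tests in this part were chosen after the patterns had been seen, except that the bound for merged peaks on X was set before its result.

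Combined peaks were crowded in a few places, mostly toward the left ends of chromosomes II and III. In windows of 50 kb the mean was 1.83 peaks, and 12 windows held 10 or more, where random placement gave a mean of 0.402 such windows and at most 3 (permutation p = 0.001, the smallest that 1000 draws can give). Chromosome III had 6 of them, II had 4, and I and X had 1 each. The fullest were III 1900001 to 1950000 with 23 peaks, and II 2200001 to 2250000 and II 2450001 to 2500000 with 19 each. The window on X, 2050001 to 2100000, held 10 combined peaks, with 15 and 13 among the first 3669 ranks of replicates 1 and 2. Moving the windows by 25 kb gave 14 of them.

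In 11 of the 12 windows both replicates exceeded the 95th percentile of their own windows, 5 peaks. The choice of windows by combined peaks favoured this, so it cannot decide whether 1 replicate alone was the source. Of all combined peaks, 68.6% lay within the first 3669 ranks of both replicates. III 2400001 to 2450000, with 5 peaks in replicate 1 and 8 in replicate 2, stays open. Windows chosen in 1 replicate passed that limit in the other in 14 of 15 cases from replicate 1 and 9 of 9 from replicate 2. For windows chosen that way, these values argue against 1 replicate alone as the source. The check and the account by window followed 2 earlier forms. The first was a bound at the highest random draw (13 peaks), which 3 of the 12 exceeded in both replicates and 6 in the combined list. The second took the 12 windows as a whole. Extra copies of the transgene's genes are excluded for the 5 windows on I and II, since unc-119 is on III and lsy-2 on X in WBcel235, and stay open for some of the 7 on III and X, where the genes were not placed in WS220. Broad raised signal split into weaker peaks is a candidate explanation for the 12 windows as a group. Of their peaks 4.76% were among ranks 1 to 500, against 14.1% outside (odds ratio 0.306, Fisher's exact p = 0.000198, treating peaks as independent). Exceptions were II 450001 to 500000 and II 2200001 to 2250000, whose median ranks of 1373 and 1759 were better than the 1810 outside, and the window on X, with 3 of 10 peaks in ranks 1 to 500; no biological explanation was tested.

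For the low X share among the 1000 highest ranked combined peaks, poorer mappability of X could not be decided on. Of the lowest 10000 ranks 16.18% were on X in replicate 1 and 16.21% in replicate 2. These lie above the upper 95% limits of the X share in their first 1000 ranks, 9.86% and 9.97%. X was thus not missing to the same degree at every rank. Chromosomes III and V also moved toward their shares of the span in the lowest ranks. A cause that weakens X peaks would also move them to lower ranks, which can hold background. Clusters of autosomal peaks do not account for the low X share: with peaks within 5 kb merged, X held 7.63% (exact 95% interval 5.96% to 9.59%), below its 17.7% of the span. A lower X dosage from males could contribute and cannot be told apart here, because no input values were analysed; X held 14.8% of the whole list of replicate 1 and 14.9% of that of replicate 2. No biological explanation was tested.

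A few strong nuclear regions were in both replicates and absent from the combined list. Of the 748 nuclear pairs ranked within 1000 in both, these were 4. They were X 5429442 to 5429561 (ranks 319 and 385), V 9175194 to 9175573 (566 and 691), I 5164808 to 5165187 (635 and 706) and II 3616625 to 3617004 (829 and 749), with coordinates from replicate 1.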
